A study of Homo sapiens with 6 samples.

How the data were processed

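RNA sequencing measured transcript levels in 6 cultures of K562, an established human erythroleukaemia cell line. Per the labels' protocols, clones carrying a doxycycline-inducible short hairpin RNA (shRNA) were kept under puromycin. Induced cultures received 1 µg/ml doxycycline and all cultures were taken at day 4, and libraries were made with the NEBNext Ultra RNA kit from total RNA. One construct was a non-targeting shRNA (NT) and the other targeted CDAN1, in clones named c1 and c2. Each of the 3 clones gave 1 induced and 1 uninduced library, so the groups held 2 induced CDAN1 shRNA libraries, 2 uninduced CDAN1 shRNA libraries, 1 induced NT library and 1 uninduced NT library. Groups were taken from the sample titles, which name the second CDAN1 clone c2, while its file names carry C3.

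Transcript abundance had been estimated with Salmon 1.5.2 against the GRCh37 (hg19) build, per the submitters' processing notes. The deposited tables give, per transcript, an estimated count of reads (expected count, not a whole number) and a value in TPM (transcript abundance scaled for length and library total), per the file headers. Trimming, the transcript annotation and the library strand are not given in the sources used here. Without a stated strand, values of antisense or overlapping genes are uncertain, as are those of near-identical copies (HBA1 and HBA2, the clustered histone genes), between which the estimates divide shared reads.

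Each table listed the same 167268 Ensembl transcripts. Of these, 151039 (90.3%) matched a transcript of GENCODE release 29 by identifier, and their estimated counts were summed to 33367 genes and rounded to whole numbers. The other 16229 transcripts, holding 6.23% to 6.5% of the reads of a library, entered neither the library sizes nor the tests. GENCODE 29 lies on GRCh38, not on the authors' GRCh37, so it served for gene names and its coordinates are given as GRCh38. A filter for low counts (edgeR's filterByExpr with a smallest group of 2) left 14075 of the 21197 genes with a count above 0. Counts relative to the library total (CPM) were scaled by TMM, and log2 values used a prior count of 2. The induction response of a clone is its log2 CPM in the induced library minus that in the uninduced library. It compares 1 library with 1 and carries no test.

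Tests across genes used edgeR 4.0.16 (quasi-likelihood test, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. The design was fixed before the data were examined. The comparison named in the series' design set the 2 induced CDAN1 shRNA libraries against the 4 controls. A fit with 4 groups gave the comparisons of induced with uninduced CDAN1 shRNA clones, of the clones' response with the NT response, and of uninduced clones with uninduced NT. Each clone gave its induced and its uninduced library, so the clone pairs the samples. The check bore this out. Deviations from the mean of the 3 induced libraries correlated across genes with deviations from the mean of the 3 uninduced libraries within each clone (r = 0.608 for NT, 0.679 for c1 and 0.741 for c2). The values between clones (−0.196 to −0.477) are pushed below 0 by centring on 3 libraries and add no evidence. Fits with the clone as a replicate block are therefore given beside each count of calls. They keep 2 residual degrees of freedom for knockdown against all controls and 1 once doxycycline is a term, so their p-values lean on the spread shared across genes. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as further tools, unblocked and blocked. The blocked edgeR fits at the main settings, with and without doxycycline, were planned, and all other blocked fits were added after the results were seen.

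The tests were tried on data simulated from the real genes' means and library sizes, with 200 changed genes in each of 5 draws. For knockdown against all controls, the unblocked edgeR test found 36.7% of genes changed 2-fold and 73.3% of those changed 4-fold among 14116 genes, and 0% of its calls were false. For induced against uninduced clones, the unblocked test found 0% and 29.7%. With the block it found 72.5% and 91.5%, with 24.8% of its calls false. Calls made by edgeR, DESeq2 and voom alike found 63.9% and 82.4%, with 8.1% false. Blocked DESeq2 alone found 64.5% and 83.0%, also with 8.1% false, so agreement of the tools added nothing to DESeq2 here. Genes called by all 3 tools lead the account of that comparison, as a list shorter than that of edgeR and no surer than that of DESeq2. Of genes changed 1.5-fold, the unblocked tests of these 2 comparisons found 2.4% and 0%. All 3 tools with the block found 34.3% in the second. For the clones' response against the NT response, the unblocked test found 0% even at 4-fold. The draws held independent genes, the same change in both clones and no doxycycline response. These shares may therefore not carry over to the real libraries.

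The 33 gene lists were fixed before the data were examined and tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation and fry beside it. For single clones, a list's median response was placed among those of 10000 random lists matched on size and mean expression. The random lists hold genes drawn independently, so a list whose genes move together reaches an extreme percentile more easily. The genes named follow a rule fixed in advance: CDAN1 first, then the largest changes among called genes with a mean log2 CPM of at least 1, or the 5 smallest p where none were called, and up to 4 members of each list. The same rule was applied to the blocked fits after the results were seen, and other genes called by all 3 tools were also chosen after their values were seen.

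Alternatives covered the normalisation, the tool, the filter, an offset for average transcript length, the removal of mitochondrially encoded and histone genes, a fold threshold, doxycycline as a covariate, each library left out, and the unmatched transcripts kept as features. Sequence searches used the 3′ untranslated region (UTR) of 1 GENCODE 29 transcript per gene. Total estimated counts ran from 28318555 to 32352246 per library. Intervals given for single libraries are exact 95% intervals and cover counting error only, because reads without molecular identifiers are not independent molecules.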

Results

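Transcript abundance was estimated in 6 libraries of K562 cells, an erythroleukaemia line that expresses embryonic and fetal globins. The series was designed to compare cells depleted of CDAN1, whose inherited mutations cause a congenital dyserythropoietic anaemia, with uninduced clones and with cells carrying a non-targeting shRNA. The uninduced libraries held 28650731 estimated reads for NT, 30759147 for c1 and 30922566 for c2. The induced libraries held 28318555 for NT, 32352246 for c1 and 31804735 for c2. Mitochondrially encoded transcripts took between 4.31% and 6.11% of the reads of a library. Each clone and condition was sampled by 1 culture, so p-values measure only the spread between these libraries.

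CDAN1 (ENSG00000140326, chromosome 15, 42723544 to 42737128 on GRCh38) was lower in the induced library of both CDAN1 shRNA clones than in any of the 4 controls. It stood at 17.0 CPM in induced c1 against 37.0 in uninduced c1, and at 29.8 CPM in induced c2 against 55.4 in uninduced c2. The NT libraries held 62.5 CPM uninduced and 70.2 CPM induced. The induced level was thus 45.8% of the uninduced level in c1 (95% interval 41.1 to 51.0), 53.7% in c2 (49.4 to 58.3) and 112.3% in NT (105.1 to 120.0). The 2 knockdown libraries averaged 23.4 ± 9.0 CPM (SD, n = 2) and the 4 controls 56.3 ± 14.2 CPM (SD, n = 4). Before induction CDAN1 already differed between clones, since uninduced c1 held 59.2% and uninduced c2 88.7% of the uninduced NT level.

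**Figure D1:**
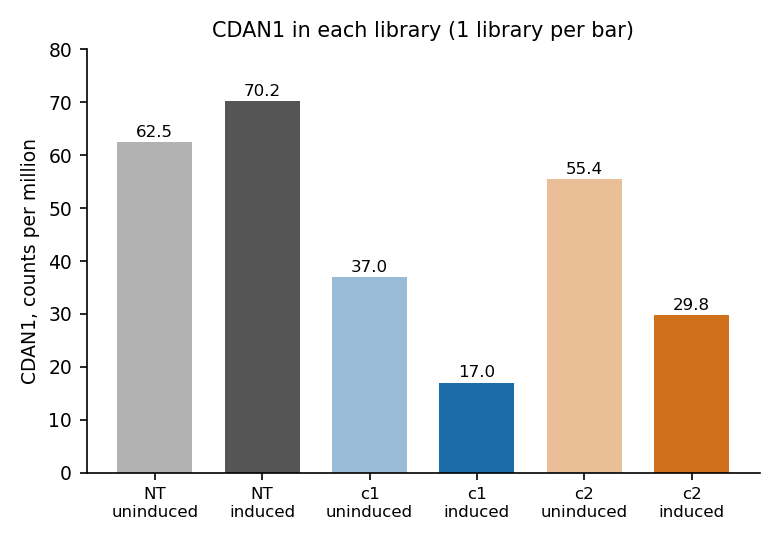
CDAN1 level in CPM (vertical axis) in each of the 6 libraries (bars, 1 library each; pale bars uninduced, dark bars induced). Induced c1 and c2 stand at 17.0 and 29.8, below the control libraries, which span 37.0 to 70.2.

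The main coding transcript, CDAN1-201, carried most of these reads. Its TPM in the induced library was 43.5% of that in the uninduced library for c1, 47.6% for c2 and 120.9% for NT. The transcript CDAN1-202, annotated for nonsense-mediated decay, stood at 58.7%, 75.7% and 83.4%. The retained-intron transcript CDAN1-204 stood at 79.4% in c1 and 205.9% in c2, from 32.5 estimated reads in uninduced c2 and 69.9 in induced c2. Summed as TPM, CDAN1 stood at 65.0% in c1, because a transcript of 285 bases with 3.0 estimated reads in the induced library weighs heavily in that unit.

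Knockdown against all controls, the comparison named in the design, had MRE11 as its gene of smallest p. MRE11, a nuclease of DNA double-strand break repair, had a log2 fold change of −1.19 ± 0.12 (SE, 2 against 4 libraries), with 20.6 and 25.7 CPM in the knockdown libraries and between 51.0 and 55.3 CPM in the controls. NAP1L4, a histone chaperone of the nucleosome assembly family, followed at −0.53 ± 0.07, and CENPM, a centromere protein, at −0.95 ± 0.16. ZNF625-ZNF20 and UBE2Q2P2 were listed at 0 in both knockdown libraries and at no more than 2.06 and 0.525 CPM in any control. None of these passed the test: edgeR's quasi-likelihood test called 0 of 14075 genes (smallest adjusted p = 0.444, for MRE11), with 322 genes at an unadjusted p under 0.05 where chance gives 704. DESeq2 called 14 genes (1 higher, 13 lower) and voom 0. CDAN1 itself had a log2 fold change of −1.27 ± 0.32 in this fit.

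With the clone as a replicate block, 6 genes were called, and DESeq2 and voom called each of them under the same block. Under this block the NT libraries do not enter the fold change, which compares induced with uninduced c1 and c2. The response of the NT pair adds only to the residual spread, so an effect of doxycycline is not taken off. AHNAK, a very large scaffold protein, rose by 0.89 ± 0.07 on the log2 scale (adjusted p = 0.0198, edgeR). MRE11 fell by 1.15 ± 0.10 (adjusted p = 0.0198), CDAN1 fell by 1.01 ± 0.10 (0.0275), SYNC fell by 0.91 ± 0.10 (0.0365), VPS26A, a subunit of the retromer, fell by 0.68 ± 0.06 (0.0256), and NAP1L4 fell by 0.52 ± 0.05 (0.0365), all by edgeR. With doxycycline as a further term CDAN1 alone of the 6 was called, and the adjusted p was 0.0648 for AHNAK, 0.05003 for MRE11, 0.111 for VPS26A, 0.232 for NAP1L4 and 0.243 for SYNC. In the NT pair the same genes moved by 0.20 for AHNAK, −0.02 for MRE11, 0.17 for CDAN1, −0.07 for SYNC, 0.00 for VPS26A and −0.01 for NAP1L4. Under the block DESeq2 called 115 genes and voom 16, and edgeR called 0 with transcript length as an offset, without a filter on low counts, with unmatched transcripts kept, or without uninduced c1, induced c1 or induced c2. It called 2 genes without uninduced c2, neither among the 6, so none of the 6 was called without any 1 of the CDAN1 shRNA libraries. It called 110 without uninduced NT and 166 without induced NT, all 6 among them each time. In simulated data 11.8% of the blocked calls of this comparison were false.

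Histone genes stood out among the lists in this comparison. The 28 replication-dependent histone genes, which package newly made DNA, fell as a list (camera, adjusted p = 0.000194, or adjusted p = 0.997 with an estimated correlation; median log2 fold change −0.197). HIST2H2BE stood at −0.50 ± 0.16, HIST1H2BD at −0.33 ± 0.11 and HIST2H2AA3 at −0.38 ± 0.14, and no member was called alone. The median of the same list was also −0.364 in the NT pair, against −0.262 in c1 and −0.246 in c2 (percentile 0.0 among matched random lists in each). The list of 32 histone chaperones was also called lower (camera, adjusted p = 0.0128, or adjusted p = 0.606 with an estimated correlation), with a median log2 fold change of only −0.040. In the induction response 13 of the 32 were positive in c1 and 13 in c2. NAP1L4 was called when adjusted over the list alone. SUPT16H, a subunit of the FACT complex, stood at −0.30 ± 0.09 and ASF1A, which hands histones H3 and H4 to other chaperones, at −0.36 ± 0.14. Of 33 lists, 2 were called at the preset correlation, 6 with the replicate block and 0 with doxycycline as a covariate. With an estimated correlation 0 were called, with or without the block.

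Induced against uninduced CDAN1 shRNA clones, with the clone as a replicate block, again had CDAN1 (−1.01 ± 0.09, adjusted p = 0.00285, edgeR) and MRE11 (−1.15 ± 0.10) among the genes that fell, and AHNAK (0.89 ± 0.06) among those that rose. GSR, which regenerates reduced glutathione, rose by 0.79 ± 0.10, LTBP4, a matrix protein that binds latent TGF-beta, by 0.74 ± 0.12, and COL18A1, a basement membrane collagen, by 0.71 ± 0.06. UTRN fell by 0.92 ± 0.13, TGFBR3, a TGF-beta co-receptor, by 0.77 ± 0.09, RAB8B by 0.76 ± 0.09, SCG3 by 0.76 ± 0.07 and YIPF6 by 0.71 ± 0.09. CDC23, a subunit of the anaphase-promoting complex, fell by 0.55 ± 0.09, the RNA helicase DDX5 by 0.52 ± 0.06 and G3BP2, a stress granule protein, by 0.46 ± 0.06. These genes belong to 59 (11 higher, 48 lower) called by edgeR, DESeq2 and voom alike.

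The NT pair, with doxycycline but without the CDAN1 shRNA, had the same sign for 48 of the 59 genes, and for 16 it was under 0.25 of their change in size. It stood at −0.49 for SCG3, 0.31 for COL18A1, −0.24 for DDX5, 0.20 for AHNAK, −0.17 for UTRN, 0.17 for CDAN1, −0.02 for MRE11, 0.12 for GSR, 0.07 for LTBP4, 0.14 for TGFBR3, 0.33 for RAB8B, 0.10 for YIPF6, 0.08 for CDC23 and 0.10 for G3BP2. It stood at −0.87 for FRYL, whose fall in the clones was 0.94 ± 0.10, at 0.73 for LMNB2 (rise of 0.50 ± 0.07), at 0.37 for HSPG2 (rise of 0.40 ± 0.06) and at −0.39 for MEF2C (fall of 0.39 ± 0.06). HGSNAT fell by 2.10 ± 0.22, but held 31.7 CPM in uninduced c1 and 1.51 CPM in uninduced c2, and its pairs stood at −2.34 in c1, −1.24 in c2 and 2.59 in NT. In the unblocked fit HGSNAT stood at 1.18 without uninduced c1, when libraries of different clones are set against each other.

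**Figure D2:**
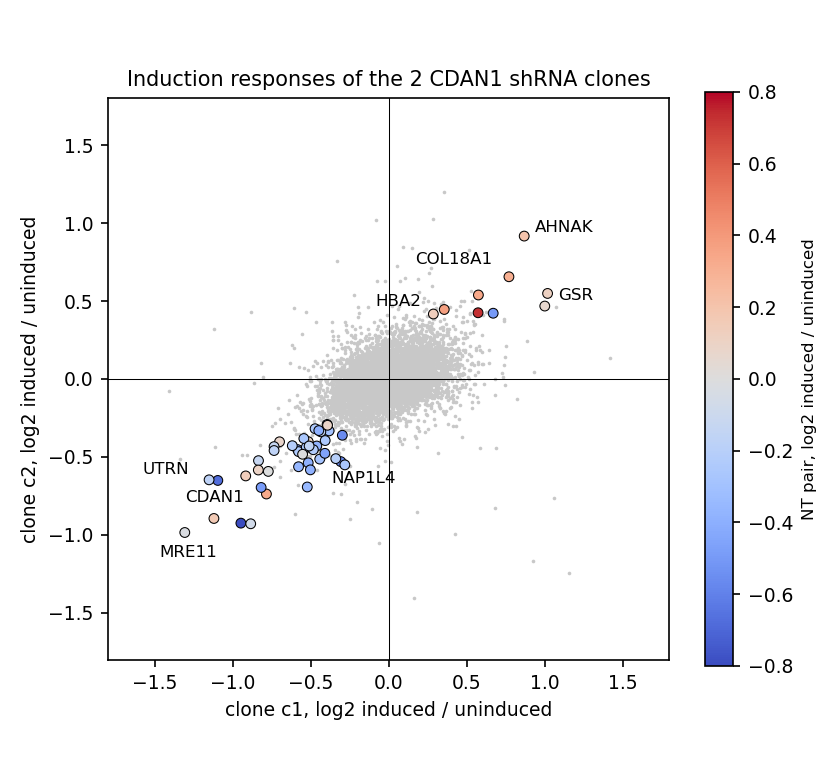
Induction responses of c1 (horizontal axis, log2 induced over uninduced) and c2 (vertical axis) for genes with a mean log2 CPM of at least 4 (grey points; 5 of 8081 genes lie outside the axes). Circles are the 52 of these genes called by all 3 tools under the block, coloured by the response of the NT pair; CDAN1, MRE11 and NAP1L4 lie in the lower left and AHNAK, COL18A1 and GSR in the upper right.

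The largest blocked changes by the fixed rule, chosen after the unblocked test made no call, included several genes under 20 CPM in most libraries. Besides HGSNAT and MRE11, SH2D1B fell by 1.38 ± 0.15, RAB5C by 1.34 ± 0.25 and CCDC80 by 1.21 ± 0.22. TIMM23B rose by 1.86 ± 0.32, USP47 by 1.21 ± 0.23, USP28 by 1.17 ± 0.16 and TAB2 by 1.08 ± 0.20. RAB5C, CCDC80 and all of these 4 that rose were called by edgeR but not by all 3 tools. RELB stood at 0 CPM in both uninduced clones and at 1.95 and 1.73 CPM when induced, while the NT pair went from 1.54 to 0.225 CPM. AC120057.2 and ZNF625-ZNF20 were listed at 0 in both induced clones and SLC2A3P1 in both uninduced clones, all with at most 2.98 CPM in any library. AC120057.2 fell in the NT pair as well (log2 −4.96, against −4.44 in c1 and −4.43 in c2). The NT pair stood at 1.02 for ZNF625-ZNF20 and went from 2.98 to 0 CPM for SLC2A3P1.

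Without the block, edgeR called 0 of 14075 genes in this comparison (207 at an unadjusted p under 0.05, DESeq2 2, voom 0), with MRE11, RELB, AC120057.2, SLC2A3P1 and SCG3 at the smallest p. With it edgeR called 141 (35 higher, 106 lower), DESeq2 65 and voom 97. The blocked edgeR call ended with transcript length as an offset (0 genes, 1314 at an unadjusted p under 0.05). It also ended with unmatched transcripts kept as features (0 genes, 1479). All 59 genes kept their sign in both fits, and 58 and 59 of them had an unadjusted p under 0.05. Their median adjusted p was 0.231 and 0.56 (edgeR). The 59 were chosen for small p in the same libraries, so their signs and unadjusted p lend no support.

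Across 8081 genes the responses of c1 and c2, which share no library, correlated at r = 0.387. Each correlated less with that of NT (0.188 for c1 and 0.185 for c2). By 2 other measures the gap was smaller. Rank correlations were 0.384 for c1 and c2, 0.272 for c1 and NT and 0.273 for c2 and NT. Signs matched in 63.3%, 60.1% and 59.5% of genes, in the same order. All of these values run across genes, which are not independent replicates. Libraries of 1 clone correlated at 0.986 to 0.988 and libraries of different clones at 0.954 to 0.969. The first principal components separated the clones (46.4% and 30.6% of the variance), and the third (9.2%) separated induced from uninduced libraries, from −27.4 to 26.7 in c1, −12.4 to 14.4 in c2 and −5.8 to 4.5 in NT.

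Among histone chaperones, 3 of 32 were called lower in the blocked comparison and none higher. NAP1L4 fell by 0.52 ± 0.06 (adjusted p = 0.00703, edgeR), SUPT16H by 0.35 ± 0.06 (0.0347) and ASF1A by 0.46 ± 0.08 (0.0305), and the first 2 were called by all 3 tools. The NT pair stood at −0.01, 0.09 and −0.19. The histone genes HIST1H1C and HIST1H2AC fell by 0.36 ± 0.06 and 0.40 ± 0.07, and the NT pair stood at −0.29 and −0.24. Adjusted over the list alone, 5 of 28 histone genes fell and 1 rose, HIST2H2BE (−0.51 ± 0.10) among the former. By camera both lists were called under the block (adjusted p = 0.000367 for the histones and 0.0188 for the chaperones) but not with an estimated correlation (adjusted p = 0.853 for both).

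A few erythroid genes rose in the induced clones. HBA2, an alpha globin, rose by 0.35 ± 0.06 (adjusted p = 0.0344, edgeR with the block), to 799 CPM in c1 and 371 CPM in c2, and ALAS2, the erythroid enzyme that starts haem synthesis, rose by 0.37 ± 0.07 (0.0484), but was not called by all 3 tools. The embryonic globin HBZ stood at 0.29 ± 0.06 and HBA1 at 0.21 ± 0.06, both called only when adjusted over the list alone, while HBD stood at −0.58 ± 0.14 and was called lower on the same terms. The NT pair stood at 0.13 for HBA2, 0.10 for ALAS2, 0.08 for HBZ and 0.12 for HBA1. As a list, the 10 globins were called higher by camera under the block (adjusted p = 0.0496), and so were the 30 red cell membrane and blood group genes (0.0142). With an estimated correlation neither was called (adjusted p = 0.853 for both). Of the 30, 8 were called higher and 3 lower when adjusted over the list alone, 0 over all genes. The former included the membrane protein EPB42 (1.37 ± 0.33), carbonic anhydrase CA1 (0.58 ± 0.13) and the Rh antigen gene RHCE (0.46 ± 0.09), and the NT pair stood at 0.68, 0.18 and 0.28. Camera called neither list in the difference from the NT response with the block (adjusted p = 0.774 for the globins and 0.362 for the red cell list). Clones differed in these genes before induction. Uninduced c2 held 1230 CPM of HBA1 and 852 CPM of HBZ, against 2290 to 2480 and 1750 to 1850 CPM in the other 3 controls. Without the block, HBA2, HBA1, HBZ and ALAS2 turned negative without induced c1 or uninduced c2, and HBD stood at 0.09 without uninduced c2.

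The 18 megakaryocyte and platelet markers fell as a list under the block (camera, adjusted p = 0.00225), with medians of −0.480 in c1, −0.140 in c2 and −0.237 in NT. This call also ended with an estimated correlation (adjusted p = 0.853). RAB27B, a small GTPase of platelet granule release, fell by 0.86 ± 0.15 with the NT pair at −0.47, but was not called by all 3 tools. In knockdown against all controls the median of this list was 0.259 while its test pointed down, and it was not called (adjusted p = 0.827, camera). Among granulocyte and monocyte markers LYZ, or lysozyme, fell by 0.48 ± 0.07 (NT −0.29) and CD68 by 0.56 ± 0.10 (NT −0.12), while the list of 10 was not called (adjusted p = 0.494, camera with the block). CD68 was not called by all 3 tools, and the list's medians were 0.069 in c1, 0.169 in c2 and −0.206 in NT. Among stem cell markers MECOM, a transcription factor of haematopoietic stem cells, fell by 0.73 ± 0.11 (adjusted p = 0.0169, edgeR), with the NT pair at 0.18, but was not called by all 3 tools. Without the block, CD68 and RAB27B turned positive without induced c1 or uninduced c2, when libraries of different clones are set against each other. MYB, a transcription factor of immature blood cells, had a log2 fold change of −0.36 ± 0.10 in knockdown against all controls and ERMAP, a blood group antigen, 0.28 ± 0.11, and neither was called.

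Of the 33 lists, 7 were called under the block. The ATF4 targets rose (camera, adjusted p = 0.00454, or 0.853 with an estimated correlation), though their median was 0.242 in c1 and −0.057 in c2. The glycolysis and hypoxia list fell (camera, adjusted p = 0.00709, or 0.853 with an estimated correlation), with the glucose transporter SLC2A3 down by 0.34 ± 0.06 (NT −0.31). Among NRF2 targets AKR1C1, an aldo-keto reductase, fell by 0.67 ± 0.10 (NT 0.08) but was not called by all 3 tools. It stood at 0.50 in the unblocked fit without uninduced c1, and the list was not called (adjusted p = 0.494, camera with the block). Camera called neither the S phase list (adjusted p = 0.494), nor the G2 and M phase list (0.494), nor the p53 targets (0.494), nor the cell death genes (0.628) in this comparison.

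Of 82 genes called lower in the blocked comparison of induced with uninduced clones and with a searchable 3′ UTR, 41 (50%) carried ACTCCAT or CTCCATA, against 1096 of 7841 genes not called (14%) and 0 of 26 called higher. These sequences are parts of a word chosen after the values were seen, from the c2 response that also enters the calls, so the shares carry no test. The median 3′ UTR was 1452 bases in the genes called lower and 978 in those not called, and the ratio of shares was 3.58, against a median of 1.43 and a next highest of 2.77 over 560 words of the same letters. MRE11, NAP1L4, SUPT16H, ASF1A, VPS26A, TGFBR3, RAB8B, CDC23, YIPF6, G3BP2, FRYL, MECOM, RAB27B, AKR1C1 and SLC2A3 were among the genes with such a sequence, and CDAN1, SYNC, DDX5, LYZ, CD68, UTRN and SCG3 had none there. CDAN1 had 1 such sequence before its 3′ UTR. CENPM, CCDC80, HGSNAT, RAB5C and SH2D1B had one in the 3′ UTR but lay outside the search.

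**Figure D3:**
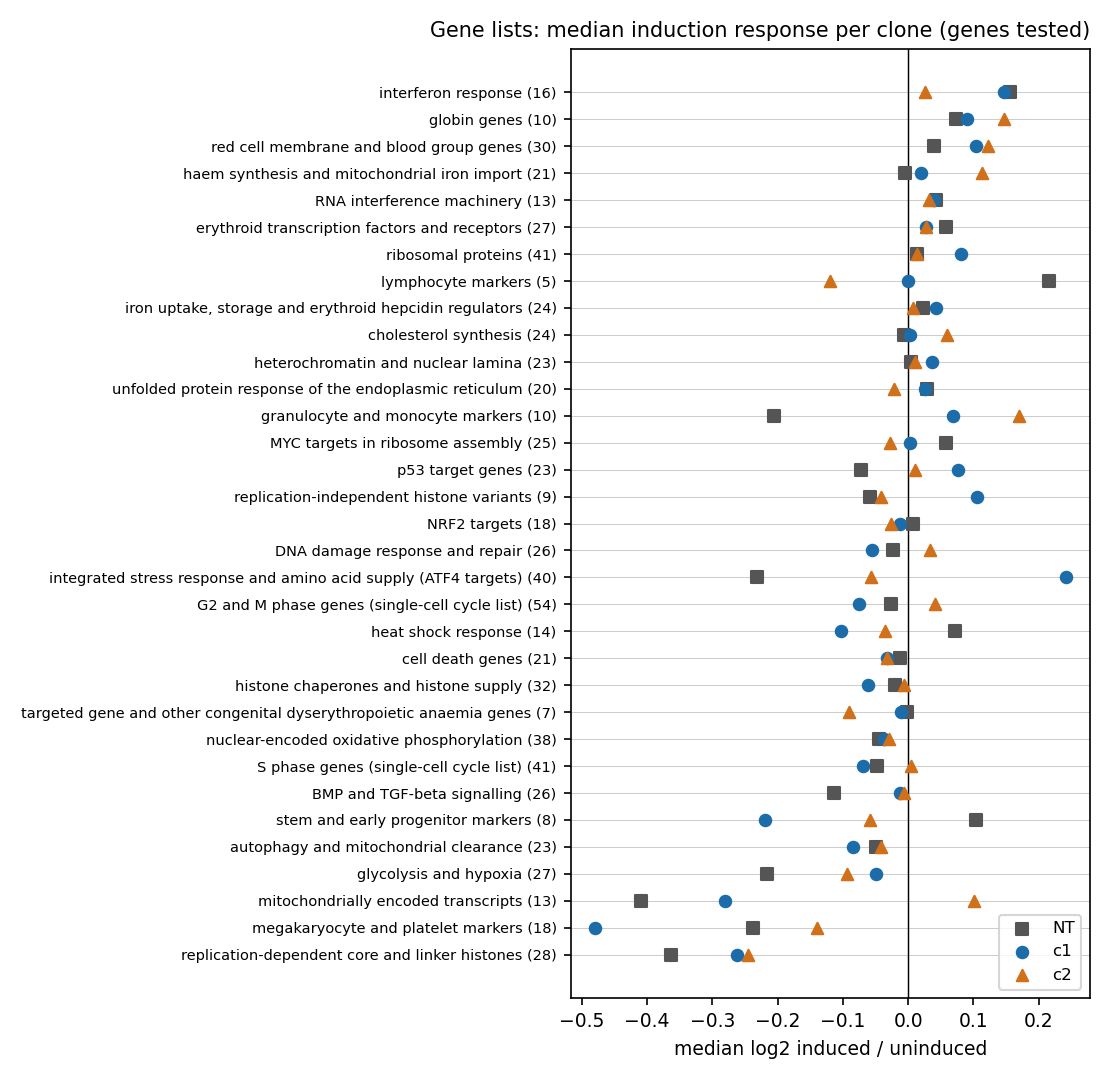
Median induction response (horizontal axis, log2 induced over uninduced) of each of the 33 gene lists (vertical axis, number of genes tested in brackets) in NT (squares), c1 (circles) and c2 (triangles), 1 pair of libraries each. Replication-dependent histones lie between −0.364 and −0.246 in all 3, while ATF4 targets lie at −0.232 in NT, −0.057 in c2 and 0.242 in c1.

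The 40 targets of ATF4, the transcription factor of the integrated stress response, were higher in the clones' response than in the NT response (camera, adjusted p = 2.25e-15, or 1.04e-18 with the replicate block), with medians of −0.232 in NT, 0.242 in c1 and −0.057 in c2, and so were the 13 mitochondrially encoded transcripts (7.72e-08 and 7.51e-10), with medians of −0.410, −0.281 and 0.101. Neither list was called with an estimated correlation (adjusted p = 0.807, or 0.909 with the block, for both). DDIT4, an inhibitor of mTOR signalling, went from 702 to 398 CPM in NT, from 228 to 308 in c1 and from 358 to 323 in c2. SLC7A5, an amino acid transporter, stood at −0.31, 0.47 and 0.04, SESN2 at −0.74, 0.17 and −0.38 and JDP2 at −0.67, 0.80 and 0.25. With the block, 9 of the 40 were called higher when adjusted over the list alone and 0 over all genes.

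Heat shock genes were lower in the clones' response (camera, adjusted p = 0.00087, or adjusted p = 0.807 with an estimated correlation), with medians of 0.071 in NT, −0.103 in c1 and −0.035 in c2. The glycolysis and hypoxia list (0.0273; −0.217, −0.050 and −0.094) and the histones (0.0258; −0.364, −0.262 and −0.246) were higher, in that their values were less negative than in NT. Neither was called with an estimated correlation (adjusted p = 0.807 for both).

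EdgeR called 0 of 14075 genes without the block (79 at an unadjusted p under 0.05, DESeq2 6, voom 0), with SLC5A3, CCDC57, SLC2A3P1, RYR1 and RELB at the smallest p, and 19 with the block (6 higher, 13 lower; DESeq2 8, voom 9). Of these, CDAN1 (−1.17 ± 0.16, adjusted p = 0.0286, edgeR) and RAB8B (−1.09 ± 0.15, 0.0318) were lower in the clones' response, and URI1 (1.04 ± 0.14, 0.0297) and ATF6B (1.18 ± 0.16, 0.0297) higher. MRE11 stood at −1.12 ± 0.17 (adjusted p = 0.05003) and missed the threshold. This blocked fit is the same test as the blocked knockdown against all controls with doxycycline as a further term. For ATF6B, RBM15B, TWF1, RYR1, TANC1 and CCDC57 the larger change was that of the NT pair: TWF1 went from 1.77 to 37.6 CPM in NT, and from 5.28 to 5.38 in c2. ATF6B went from 93.5 to 53.6 CPM in NT, from 55.9 to 64.1 in c1 and from 78.9 to 116 in c2. In simulated data 26.4% of the blocked calls of this comparison were false, and the unblocked test found 0% of genes changed 4-fold.

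Uninduced CDAN1 shRNA clones were set against uninduced NT cells to measure how the clones stood before induction. NAP1L5 stood at 17.2 CPM in uninduced c1 and 17.9 CPM in uninduced c2 against 1.39 CPM in uninduced NT, and UGT8, an enzyme of galactolipid synthesis, at 16.4 and 18.2 against 2.30 CPM. TSPAN6 stood at 0.212 and 0.171 CPM against 9.95 CPM and RYR1 at 16.2 and 11.9 against 0.339 CPM. Induced NT held 4.91 CPM of RYR1, so part of that gap rests on the uninduced NT library alone. These genes were among those with the smallest p and none passed the test, which set 2 libraries against 1: edgeR called 0 of 14075 genes (smallest adjusted p = 0.73, 777 at an unadjusted p under 0.05), DESeq2 62 and voom 0. CDAN1 stood at −0.44 ± 0.42 in this fit.

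Induced NT cells, compared with uninduced NT cells as 1 library with 1 and without a test, had few genes far from their uninduced level. Of 8081 genes, 11 differed over 2-fold, against 17 in c1 and 9 in c2. Doxycycline, the induced NT hairpin and differences between the cultures cannot be told apart in this pair. The SD of the responses was 0.185 in NT, 0.210 in c1 and 0.152 in c2. Among the lists, the medians of the histones (−0.364), the mitochondrially encoded transcripts (−0.410), the ATF4 targets (−0.232) and the glycolysis and hypoxia genes (−0.217) in NT lay at the percentile 0.0 of matched random lists. The mitochondrially encoded transcripts lay at 0.0 in c1 and at 100 in c2, and the ATF4 targets at 100 in c1 and at 0.7 in c2. These percentiles take no account of genes of a list moving together, nor of differences between cultures. The highest in NT were the MYC targets in ribosome assembly (99.7), the heat shock genes (99.6), the erythroid transcription factors and receptors and the interferon response genes (99.2 each).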

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

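The tests of explanations in this part were all chosen after the results were seen; the tests of the differences themselves were fixed in advance, both without and with the clone as a replicate block.

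In the difference between the induction response of the CDAN1 shRNA clones and that of NT, tested by edgeR with the replicate block, several genes had 1 NT library near 0. SLC5A3, a myo-inositol transporter, was listed at 0 CPM in uninduced NT and at 40.1 CPM in induced NT, at least 354-fold higher against a floor of 3 counts per library (0.113 CPM), and its fitted difference of −13.73 is no bound. The differences were −4.72 for HGSNAT, −4.11 for TWF1, −3.95 for RYR1 and −2.06 for TANC1, each with at most 2.86 CPM in uninduced NT, and −2.12 for RBM15B and −1.58 for CCDC57, with 22.4 and 43.2 CPM there. Shared reads between near-identical or overlapping transcripts may account for part of the 19 genes: 6 (31.6%) had over 50% of their 31-base words in other genes, against 34 of 380 matched genes (8.9%; Fisher's exact test, p = 0.00707). The median over the 19 was 1.0%, which argues against reads shared with matched transcripts of the same strand for most of them. The search could not see sharing with the 16229 unmatched transcripts or with antisense genes, so it does not decide on those. What separates those libraries stays open.

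The differences of CDAN1 (−1.17), RAB8B (−1.09), URI1 (1.04) and ATF6B (1.18) did not rest on a library near 0. For ATF6B the larger change was that of the NT pair, from 93.5 to 53.6 CPM.

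Targets of ATF4 were higher in the clones' response than in the NT response (camera with the block, adjusted p = 1.04e-18, or 0.909 with an estimated correlation). The c1 response lay above that of c2 in 36 of 40 members, with a median difference of 0.33, and 37 of 40 were positive in c1 against 13 in c2 and 6 in NT. An effect of CDAN1 knockdown that is alike in both clones cannot be told apart from differences between cultures, since 1 culture per clone and condition leaves the spread between cultures unknown. The other lists with a different response were the mitochondrially encoded transcripts (7.51e-10), heat shock genes (0.000909), glycolysis and hypoxia (0.00385) and replication-dependent histones (0.0263), all adjusted p by camera with the block, and none was called with an estimated correlation (adjusted p = 0.909 for each).

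Among the 4 controls, 13 of 73 named genes had 1 library far from the other 3, where chance gives about 1 in 20 (3.6 genes) if the 4 libraries are independent. They were not, since both NT libraries come from 1 clone and the clones differ, so 3.6 is not the number to expect here. The genes were not independent either, and several were named because of their values. The gap to the nearest control, as a share of the whole range, is given for each. Uninduced c1 stood apart for CD68 (0.875; 20.4 CPM against 51.6 to 56.0), MECOM (0.848; 33.5 against 17.6 to 20), VPS26A (0.848; 203 against 145 to 154), TGFBR3 (0.844; 85.9 against 52.0 to 57.3) and G3BP2 (0.833; 212 against 147 to 158). Uninduced c2 stood apart for HBZ (0.905; 852 CPM against 1750 to 1850), HBA1 (0.842; 1230 against 2290 to 2480) and AKR1C1 (0.881; 10.6 against 34.5 to 37.8). Uninduced NT stood apart for SLC2A3P1 (1.0; 2.98 CPM against 0), URI1 (0.857; 85.7 against 60.8 to 64.4) and RELB (0.854; 1.54 against 0 to 0.225). Induced NT stood apart for UBE2Q2P2 (0.92; 0.525 CPM against 0.377 to 0.389) and CCDC57 (0.844; 140 against 25.4 to 43.2).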

How the results depend on the processing

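The replicate block with edgeR at its main settings, with or without the doxycycline covariate, was planned. All other blocked alternatives, and those that kept unmatched transcripts, were chosen after seeing the data; the rest were planned. Unblocked edgeR counts stayed at 0 in all 4 comparisons with RLE size factors, no filter, the length offset, a fold threshold, or without mitochondrially encoded and histone genes, and voom also called 0. In simulated data the unblocked test found 0% of genes changed 4-fold for the response difference. For induced against uninduced clones it found 0% of those changed 2-fold. A count that stays at 0 in these 2 comparisons therefore says little about stability. Counts at an unadjusted p under 0.05 with edgeR's main settings were 322, 207, 79 and 777, as ordered in the report. DESeq2 called 14, 2, 6 and 62. Doxycycline as a covariate gave 0 (313 unadjusted) and leaving out 1 library gave 0, for all 6 libraries in the first comparison and for the 4 CDAN1 shRNA libraries in the next 2, where NT libraries were not left out singly. With both NT libraries as controls, the baseline comparison called 0 (2106 unadjusted).

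With the block, knockdown against all controls gave 6 genes, 19 with a doxycycline covariate, 115 by DESeq2, 16 by voom, 6 with RLE and 70 with robust dispersion. Leaving out 1 library gave 0 to 166, including 110 and 2. Induced against uninduced clones gave 141, 65 by DESeq2, 97 by voom, 137 with RLE, 286 without a filter, 290 with robust dispersion and 138 with only the 4 CDAN1 shRNA libraries (130 shared with the 141). The length offset and unmatched transcripts kept gave 0 in both. At the main settings both take the same fold changes from c1 and c2 alone, so the 6 and the 141 are not separate results. The response difference gave 19, 8 by DESeq2 and 9 by voom. Its blocked edgeR fit is the same test as knockdown against all controls with the block and the covariate, so the 2 counts of 19 are 1 result. No CDAN1 shRNA library could be left out of the last 2 blocked comparisons, since no residual degrees of freedom remain, and the response difference needs both NT libraries. Lists called for knockdown against all controls went from 2 to 0 with an estimated correlation, 6 with the block (0 with an estimated correlation) and 0 with the covariate, and for the response difference from 5 to 0 with an estimated correlation.

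CDAN1 in the induced library, as a percent of the uninduced one, was 120.9, 83.4 and 99.1 in NT by transcripts CDAN1-201, 202 and 204. In c1 it was 65.0 by TPM, 58.7 by 202 and 79.4 by 204, and in c2 it was 47.6, 75.7 and 205.9 by 201, 202 and 204. Among the named genes, HIST2H2AA3 turned to 0.06 with the block and the covariate, and 15 values of 9 genes reversed with 1 library left out. The lowest and highest log2 values with 1 library left out were −4.79 and 1.18 for HGSNAT, −1.76 and 0.50 for AKR1C1, −1.58 and 0.36 for CD68, −0.33 and 1.08 for HBA2, −0.25 and 0.71 for HBA1, −0.32 and 0.91 for HBZ, −0.26 and 1.10 for ALAS2, −2.78 and 0.82 for RAB27B, and −1.37 and 0.09 for HBD. In these unblocked fits the lone library is assumed to vary like the other groups. Beyond the tools' own construction, the cause was not tested.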

Other observations

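The tests in this part were chosen after the results were seen.

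Genes with the sequence ACTCCATA in the 3′ UTR were lower in the induced CDAN1 shRNA clones. By z score (sum scaled by the number of genes and the spread over all genes) it was the lowest 8-base word in the c2 response, among words carried by at least 30 of the 7949 genes searched (mean log2 CPM of at least 4, each response under 3 in size). The 120 genes with it had a mean there of −0.10 ± 0.02 (SE over genes; log2, adjusted for length, with large values capped). In c1, whose libraries did not choose the word, their mean was −0.148 ± 0.023, the lowest of 560 words of the same letters. Each SE runs over genes within a single pair of libraries and does not measure the spread between cultures. A candidate explanation is that the induced hairpin silences further transcripts through a short match in the 3′ UTR, as small RNAs can. The values argue against base composition (median −0.026 over words of the same letters in c1). They also argue against doxycycline without the CDAN1 hairpin (mean 0.009 ± 0.015 in the NT pair), as far as a single NT pair can show.

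MRE11 carries the whole 8-base word, so its lower level may reflect the hairpin. The mean of −0.148 over genes with the word in c1 does not measure its own fall of 1.15. VPS26A, TGFBR3 and FRYL are among other called genes with the whole word. The NT pair stood at −0.02 for MRE11, 0.00 for VPS26A and 0.14 for TGFBR3. For FRYL it stood at −0.87, near its fall of 0.94 in the clones. NAP1L4, SUPT16H and ASF1A carry only a 7-base part of the word (ACTCCAT or CTCCATA), and the mean of −0.148 does not cover them. The hairpin's sequence, and whether c1 and c2 carry the same one, are not given in the sources used here. The 6 libraries hold no rescue, and whether they hold more than 1 CDAN1 hairpin is unknown, so the loss of CDAN1 itself stays untested as an explanation.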
